A study of Homo sapiens with 12 samples.

How the data were processed

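RNA was measured from HES2 human embryonic stem cells sorted by GCTM-2 and CD9 into the fractions p4, p5, p6 and p7, with 3 arrays per fraction and 12 arrays in all. Per the labels, total RNA was purified with a column kit and checked on a Bioanalyzer, and 100 ng was amplified and labelled with Cy3 for Illumina Human-6 version 2 arrays. The samples lay on 2 slides. Slide 1 held p4, p5, p6 and p7 of replicate 1 and p4 and p5 of replicate 2, and slide 2 held the other 6 arrays. Slide 1 thus held 2 arrays each of p4 and p5 and 1 each of p6 and p7, and slide 2 held the reverse. Fraction and slide were therefore partly confounded between p4 or p5 and p6 or p7, and the main fit had no slide term. Within a slide the lone arrays were assumed to vary like the rest. The order of the fractions was taken from their numbers.

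The deposited probe values were of 2 kinds. Per the file headers, the first were bead-averaged signal intensities from BeadStudio 2.3.41 without normalization, with the number of beads and a bead-level error. The detection score per probe was deposited as a fraction between 0 and 1 and was read as 1 minus the detection p-value, since bright probes had values of 1. The second were intensities that the authors had normalized. Their 12 columns had nearly equal distributions on a linear scale, with medians from 20.7 to 20.8. The authors' notes name BeadStudio and RMA, without versions or the role of each. Raw median signals ran from 197.9 to 244.9 and the highest signal per array from 66762 to 69332.7. A raw signal above 50000, near the scanner's ceiling, was seen on at least 1 array for 84 tested genes and on all arrays for 33, which limits how far their differences are resolved. No genome build was stated, so no coordinates are given.

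Values were computed from the non-normalized signals in R 4.3.3 with limma 3.58.1. Background correction, quantile normalization and log2 transformation used neqc with an offset of 16, with negative controls inferred from the detection p-values. Of 48687 probes, 23675 carried 1 gene symbol, 35 several and 24977 none. Probes detected at p under 0.01 on at least 3 of 12 arrays were kept (15741, of which 12615 had 1 symbol). Where a gene had more than 1 detected probe (1035 genes), the probe with the highest mean over all arrays was used, which left 11372 genes. Where the detected probes of a gene were called on their own, 124 of 462 genes with at least 2 called probes had calls in opposite directions (26.8%), so a gene's value is that of its probe. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.

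One limma fit of all 12 arrays with 4 groups gave each difference, with 8 residual degrees of freedom and an empirical Bayes prior of 3.02. P-values were adjusted by Benjamini-Hochberg over the 11372 genes of each comparison, with a threshold of 0.05. The comparisons were an F-test over the fractions, p7 against p4, p6 against p4, p5 against p4, p6 against p5, p7 against p6, and the difference between the first step (p5 minus p4) and the last (p7 minus p6). A gene whose probe was detected on none of the 3 arrays of a fraction was given a lower bound of its fold. For the bound, each of its arrays was set at the higher of the gene's own signal and the lowest signal of any detected probe on that array. Errors are standard deviations over 3 arrays or standard errors of the fit. The position of a fraction was its projection on the axis from p4 to p7, taken over all tested genes with the axis from the other 2 replicate numbers, and p5 and p6 were compared by an exact two-sided sign-flip test.

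Gene lists were written before the data were examined, and 23 had at least 5 tested genes. They were pluripotency, surface antigens, epithelial, neural, neural crest, endoderm, mesoderm, trophoblast, HOX, fibroblast and matrix, endothelial and blood, germ cell, NODAL, FGF, WNT and BMP signalling, cell cycle, DNA methylation, glycolysis, imprinted, p53 targets, immediate-early and stress, and housekeeping genes. Some genes stand in more than 1 list: 12 of the 22 tested surface antigens, 7 of the 28 tested pluripotency genes and 7 of the 24 tested mesoderm genes. Lists were tested between p7 and p4 with camera at a preset inter-gene correlation of 0.01, adjusted over the 23 lists. List means include undetected genes at their measured signal. Alternatives were an estimated correlation and fry, which asks whether a list's genes move on balance in 1 direction.

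Genes were named by a rule fixed before the data were examined. For p7 against p4 it took the 12 largest positive and 12 largest negative differences among called genes whose 3 arrays in 1 fraction all lay on the same side of the 3 in the other. It also took up to 4 called members of each list, and CD9, PODXL, POU5F1, NANOG and SOX2 whatever their test. For each other comparison it took the 5 largest of each sign and the same fixed genes. No p6-to-p7 gene other than FLRT3 passed, so no other was named there.

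The series states that 3 consecutive passages each gave the 4 fractions, and the replicate number was taken as the passage, which the labels do not state in so many words. After subtracting each fraction's mean, arrays of different fractions with the same number had a mean correlation across genes of 0.256 over 18 pairs, from -0.04 to 0.589, against -0.13 over 36 pairs of other numbers. The subtraction makes the 3 arrays of a fraction cancel out for each gene. The -0.13 therefore largely follows from the 0.256 and is not a separate comparison. Of 12 arrays, 11 correlated best with an array of their own number. Pairs with the same number on the same slide averaged 0.299 (14 pairs) and on the other slide 0.104 (4 pairs). Arrays of number 1 all lay on slide 1 and those of number 3 on slide 2, so number and slide overlap. Genes are not independent replicates in these correlations. Arrays of the same fraction correlated at 0.983 to 0.993 and arrays of different fractions at 0.883 to 0.990.

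Each result was recomputed with 1 choice changed at a time. These choices were normexp with an offset of 50, no background correction, median scaling, the authors' normalized values, no filter or detection on all 12 arrays, every probe on its own, the slide as a block or each slide alone, the replicate number as a block, both blocks, only the groups compared, a trended and robust variance, array weights, an adjusted p under 0.01, at least a 2-fold difference, and leaving out each array and each replicate number. The method was tested on simulated data for p7 minus p4, with changes placed in 4 sets of 50 among 11372 genes. It called 24 of 50 genes changed by 1.5-fold, 36 of 50 by 2-fold, 50 of 50 by 4-fold and 50 of 50 by 8-fold, and 11 of 11172 unchanged genes. Of 23 simulated lists it called 3 of 3 shifted and 0 of 20 others. Far fewer genes were changed than the 6463 called between p7 and p4 in the data, so these rates need not hold there. The noise was drawn independently for each gene, so correlation between genes and pairing of arrays were not simulated. The list result therefore does not test the preset correlation, while the estimated correlation of the HOX list was 0.582. Probes without a single gene symbol were left out of the main comparisons and entered only where every probe was tested on its own.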

Results

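Gene expression was measured in HES2 cells, an established human embryonic stem cell line, after fluorescence-activated sorting for 2 surface antigens. GCTM-2 is an antibody to an epitope on a keratan sulphate proteoglycan of the pericellular matrix, and CD9 is a tetraspanin of the plasma membrane. Cells of 3 consecutive passages were each sorted into 4 fractions, named p4, p5, p6 and p7, and the RNA of each fraction was hybridised to its own Illumina BeadChip array, which gave 12 arrays, 3 per fraction. The labels number the fractions and do not give the antigen level of each gate. Each array detected between 13878 and 15278 of 48687 probes, with a median of 38 or 39 beads per probe, and 11372 genes were tested. The number of arrays limits the precision of every comparison, and p-values measure the spread between arrays of a fraction, from passages of 1 cell line. The main fit had no term for the replicate number. Shifts shared by the 4 fractions of 1 number thus stayed in that spread. A fold marked "at least" is a lower bound, given where a fraction had the gene's probe detected on none of its 3 arrays.

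The first question was whether the 4 fractions differed at all, and how they lay relative to each other. By limma's moderated F-test, 6644 of 11372 genes differed among the fractions (58.4%). The first principal component held 69.9% of the variance and the second 10.2%. On an axis from p4 (0) to p7 (1), taken over all tested genes, p5 lay at 0.431 ± 0.0265 (SD, n = 3) and p6 at 0.891 ± 0.0362 (SD, n = 3). The p6 position was above the p5 position in each of the 3 replicate numbers, from 0.851 to 0.921 against 0.411 to 0.461 (exact two-sided sign-flip test, p = 0.25, the smallest p that 3 pairs allow). Of the 6463 genes that differed between p7 and p4, the group means ran in 1 direction through p4, p5, p6 and p7 for 3442 (53.3%). Within slide 1 the F-test called 1603 genes and within slide 2 it called 3585, with 6962 when the slide was a block.

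**Figure D1:**
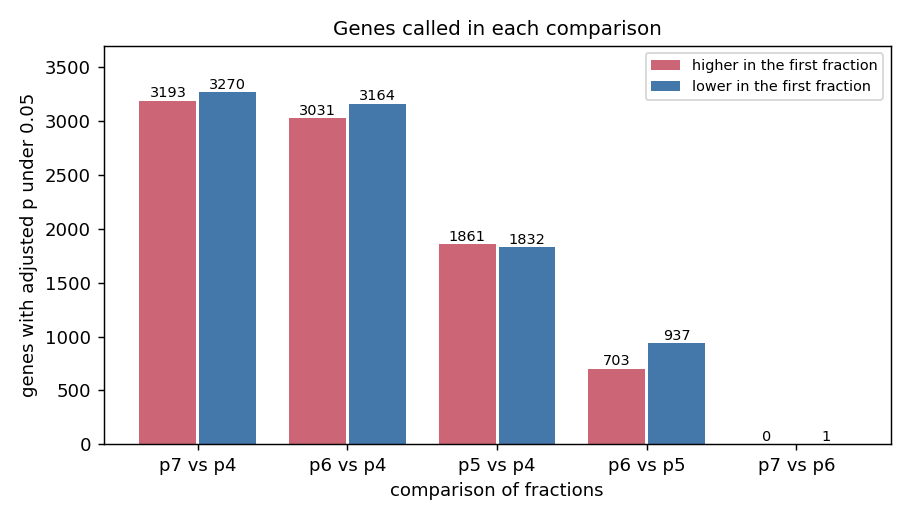
Genes with an adjusted p under 0.05 in each comparison of fractions (x axis) as a number of genes (y axis), red for genes higher and blue for genes lower in the first-named fraction. The bars fall from 3193 and 3270 genes for p7 against p4 to 0 and 1 for p7 against p6.

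The main comparison set the outer fractions against each other, p7 against p4. The genes named here are those of a rule fixed in advance, ordered by the fitted difference. The antigen gene CD9 was 6.26-fold higher in p7, with a log2 intensity of 13.89 ± 0.19 against 11.24 ± 0.37 (SD, n = 3 each, limma adjusted p = 6.96e-07). POU5F1, the pluripotency transcription factor OCT4, was 7.98-fold higher (15.80 ± 0.06 against 12.80 ± 0.59, SD, n = 3 each, adjusted p = 2.12e-06). That probe came close to the scanner's ceiling, and the other detected POU5F1 probe gave a log2 difference of 4.62. PODXL, which encodes the sialomucin podocalyxin, was 2.37-fold higher (adjusted p = 0.00266), and within slide 1, with 2 p4 arrays and 1 p7 array, its log2 difference was 1.31 (adjusted p = 0.166), against 1.25. The largest increases included GDF3, a TGF-beta family ligand, at 21.9-fold (log2 difference 4.45, SE 0.316), and EPCAM, an epithelial adhesion molecule, from 9.71 ± 0.71 in p4 to 13.71 ± 0.06 in p7 (SD, n = 3 each). MIXL1, a homeobox gene of the primitive streak, was detected on none of the p4 arrays and was at least 9.23-fold higher in p7. MGAT4C, detected on no p4 array, was at least 7.80-fold higher. HHLA2, CHST4, GAL, LNCPRESS1, CLDN7, CFAP95, RBM47 and CHGA had log2 differences from 3.46 to 4.04. SOX2 gave a log2 difference of -0.43 with an adjusted p of 0.171, from a dim probe detected on all 3 p4 arrays and on no p7 array. The NANOG probe was detected on none of the 12 arrays, so NANOG was not tested.

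**Figure D2:**
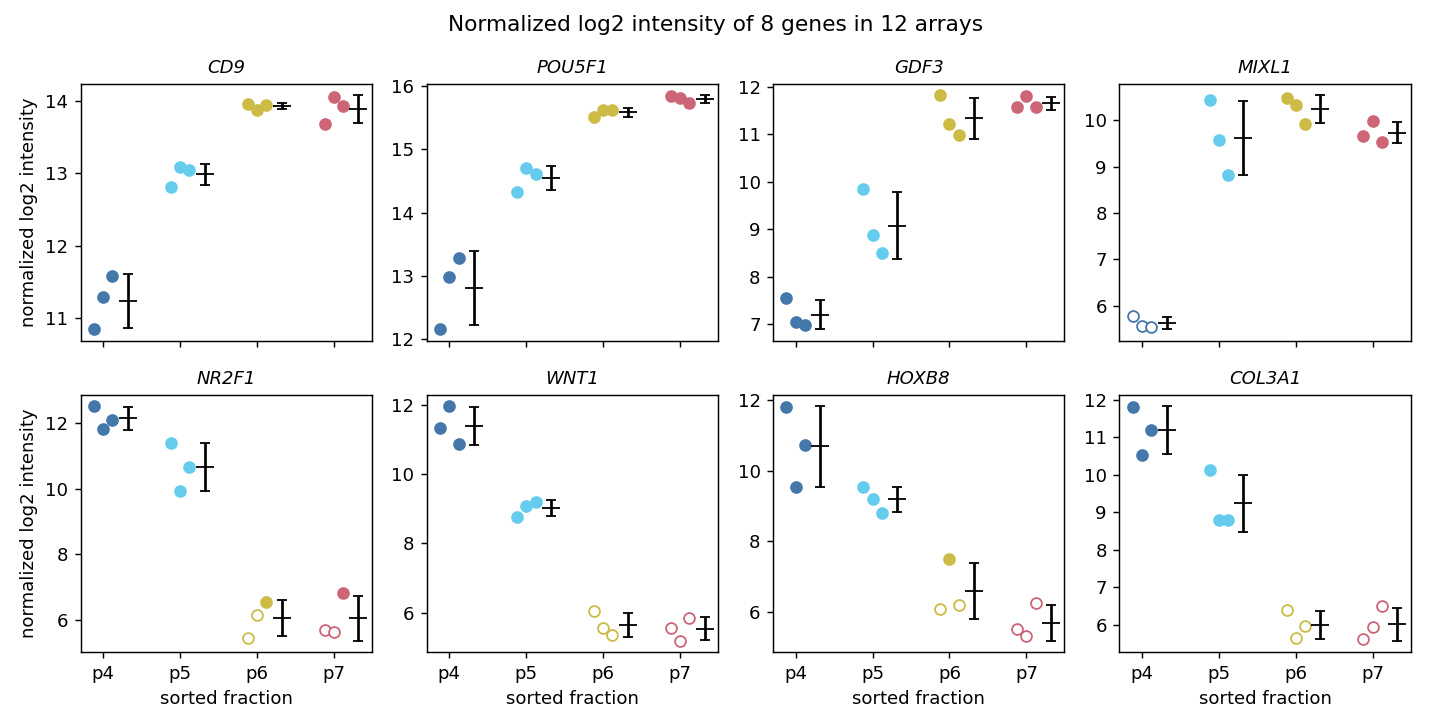
Normalized log2 intensity (y axes) of 8 genes in the 4 fractions (x axes), 1 point per array, filled where the probe was detected and open where it was not, with a black bar for the mean and SD of 3 arrays. CD9, POU5F1 and GDF3 climb from p4 to p6, MIXL1 is detected in p5, p6 and p7 only, and NR2F1, WNT1, HOXB8 and COL3A1 are detected on all p4 and p5 arrays and on at most 1 of 3 arrays in p6 and in p7.

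The named decreases include genes detected on no p7 array, which are given as bounds. NR2F1, an orphan nuclear receptor of neural development, had a log2 intensity of 12.14 ± 0.34 in p4 and 6.05 ± 0.68 in p7 (SD, n = 3 each, log2 difference -6.09, adjusted p = 1.1e-06), where 1 of 3 arrays detected it. WNT1, a midbrain patterning ligand, was at least 27.2-fold lower in p7 than p4, and POU3F2, a neural POU-domain factor, at least 28.4-fold lower. IGF2, an imprinted growth factor, was at least 26.9-fold lower, and the collagen gene COL3A1 at least 23.8-fold lower. The patterning genes HOXC6 and HOXB8 were at least 20.1-fold and 16.8-fold lower. The small proteoglycan gene LUM was at least 18.8-fold lower. ZBTB16, MMRN1 and TYRP1 were at least 21.5-fold, 14.7-fold and 16.9-fold lower. ZIC4, detected on 1 p7 array, had a log2 difference of -5.24. In total, 3193 genes were higher and 3270 lower in p7 than p4 (limma, Benjamini-Hochberg adjusted p under 0.05), of which 1043 and 1239 differed by at least 2-fold. With the slide as a block the counts were 3335 and 3384, within slide 1 they were 1221 and 1462, and within slide 2 they were 2460 and 2193.

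Of 23 gene lists fixed in advance, 11 were shifted between p7 and p4 by limma's camera with a preset inter-gene correlation, and none of the 11 held with an estimated correlation, for which the adjusted p is given beside each. In the pluripotency list, 24 of 28 tested genes rose in p7 and none fell (mean log2 difference 1.85, adjusted p = 1.29e-09, and adjusted p = 0.118 with an estimated correlation). Besides GDF3, GAL and POU5F1, the ligand gene NODAL was 8.44-fold higher (adjusted p = 0.000122). The epithelial list rose too, with 13 of 16 genes higher and 1 lower (mean 1.67, adjusted p = 5.44e-05, and adjusted p = 0.118 with an estimated correlation). Its largest members were EPCAM, the tight-junction genes CLDN7 (12.6-fold) and MARVELD3 (at least 4.66-fold) and the basement-membrane gene LAD1 (10.1-fold). The surface antigen list, with 11 of 22 genes higher and 4 lower, did not pass camera (adjusted p = 0.141). In it the chemokine receptor gene CXCR4 was lower in p7, by a log2 difference of -3.98 (SE 0.138), and the growth factor receptor gene PDGFRA was at least 3.27-fold lower.

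Of the lineage lists, neural, HOX, mesoderm and neural crest passed with the preset correlation and none with an estimated one. In the neural list, 20 of 25 genes fell in p7 and 2 rose (mean log2 difference -2.23, adjusted p = 3.84e-07, and adjusted p = 0.118 with an estimated correlation). PAX6, a master regulator of eye and forebrain development, was detected on all p4 arrays and on no p7 array, the Notch target HES5 had a log2 difference of -4.89 and the non-canonical Notch ligand gene DLK1 one of -4.50. The HOX list fell in 13 of 14 tested genes with none higher (mean -3.35, adjusted p = 2.64e-06, and adjusted p = 0.232 with an estimated correlation). Of 39 listed HOX genes, 29 had an annotated probe and 14 passed the detection filter. HOXC6 and HOXB8 passed it only through fractions other than p7, so the share covers detected genes alone. The mesoderm list fell in 16 of 24 genes and rose in 4 (mean -1.52, adjusted p = 0.000591, and adjusted p = 0.377 with an estimated correlation). Its falling members included HAND1, a cardiac and extraembryonic factor, with a log2 difference of -4.03, and MEIS1, at least 8.78-fold lower. The 4 genes that rose were MIXL1, TBXT, CDX1 and KDR. The neural crest list fell in 9 of 13 genes and rose in 3 (adjusted p = 0.0210, and adjusted p = 0.142 with an estimated correlation), with TFAP2B at least 4.73-fold lower and SOX9 at a log2 difference of -2.81. Within slide 1 and within slide 2 that list was not past the threshold (mean -1.32 and -0.83 against -1.39, adjusted p = 0.0655 and 0.165).

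Markers of other cell types moved with these lists. In the fibroblast and matrix list, 12 of 23 genes fell in p7 and 2 rose (mean -1.32, adjusted p = 0.00967, and adjusted p = 0.508 with an estimated correlation), among them COL6A3 with a log2 difference of -4.41 and DCN, at least 3.67-fold lower, which was not past the threshold within slide 1 (log2 difference -2.13, adjusted p = 0.0512). In the endothelial and blood list, 7 of 8 tested genes fell (mean -1.20, adjusted p = 0.0206, and adjusted p = 0.118 with an estimated correlation). VWF fell by the most, with a log2 difference of -2.58. Only these 8 of the 22 listed genes passed the detection filter. The probes of markers such as PECAM1 and CD34 were detected on 0 of 12 arrays. Without p4 replicate 3 the mean of that list was -1.08 (adjusted p = 0.0533). Within slide 1 neither list was past the threshold (mean -1.02 for each, adjusted p = 0.108 and 0.0728). With probes detected on all 12 arrays, a filter that drops genes undetected in p7, neither passed (mean -0.55 and -1.23). Nor did the mesoderm, neural crest and housekeeping lists (mean -1.40, -1.03 and 0.47, the last unchanged). The endoderm list, with 11 of 20 genes lower and 6 higher, did not pass (adjusted p = 0.149). Among the lower genes, the apolipoprotein gene APOA1 had a log2 difference of -4.46 and the transthyretin gene TTR was at least 2.73-fold lower. The 6 higher genes were EOMES, GSC, CER1, FOXA3, FOXA2 and LAMB1, with log2 differences from 0.31 to 2.15. Neither the trophoblast list (1 higher and 5 lower of 9, adjusted p = 0.258) nor the germ cell list (1 higher and 3 lower of 7, adjusted p = 0.723) passed.

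Among signalling lists, most WNT and BMP genes fell in p7. The WNT list fell in 17 of 25 genes and rose in 1 (mean -1.10, adjusted p = 0.000237, and adjusted p = 0.118 with an estimated correlation), with the ligand enhancer RSPO3 at a log2 difference of -4.50, the receptor FZD10 at -3.71 and the nuclear effector LEF1 at -3.26. The gene that rose was the beta-catenin gene CTNNB1, by 2.89, and the falling genes included the antagonist genes DKK1 (-2.30) and FRZB (-2.29). These 3 were chosen after their values were seen. The activity of the pathway was not measured. The BMP list fell in 15 of 20 genes and rose in 1 (mean -1.42, adjusted p = 9.7e-05, and adjusted p = 0.312 with an estimated correlation), with the ligand BMP4 at -2.77 and its target MSX1 at -3.65. The NODAL list had 8 of 16 genes higher and 3 lower (adjusted p = 0.342), with NODAL higher and its inhibitor gene LEFTY2 lower, at a log2 difference of -2.79. The inhibitor genes LEFTY1 and CER1, chosen after their values were seen, were higher, by 0.97 and 1.15 (adjusted p = 0.0207 and 0.0330). The FGF list had 7 of 18 genes higher and 5 lower (adjusted p = 0.723). FGF2, the growth factor that sustains human embryonic stem cells in culture, was at least 2.43-fold higher in p7.

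The housekeeping list, kept as a sign of RNA quality and scaling, also rose in p7, with 8 of 15 genes higher and 1 lower (mean 0.47, adjusted p = 0.0400, and adjusted p = 0.201 with an estimated correlation). ACTB rose most, 5.75-fold (log2 difference 2.52, SE 0.192), while GAPDH, chosen after its value was seen, gave -0.14, or 0.00354 with median scaling. The call of this list ended with the slide as a block (mean 0.46, adjusted p = 0.0539), within slide 1 and within slide 2 (mean 0.48 and 0.41, adjusted p = 0.0758 and 0.111), and without p4 replicate 1 (mean 0.44, adjusted p = 0.0724). The cell cycle list had 13 of 39 genes higher and 6 lower (adjusted p = 0.113), led by RRM2, a subunit of ribonucleotide reductase, at 4.22-fold. It passed with median scaling (mean 0.32, adjusted p = 0.0414) and without the filter on dim probes (mean 0.25, adjusted p = 0.0422). The endoderm list passed without that filter (mean -0.78, adjusted p = 0.0236). The DNA methylation list (3 higher and 2 lower of 8, adjusted p = 0.723), the glycolysis list (1 higher and 6 lower of 19, adjusted p = 0.335), the imprinted list (3 higher and 6 lower of 13, adjusted p = 0.102, but 0.0480 for probes detected on all 12 arrays and 0.0496 within slide 1), the p53 target list (4 higher and 2 lower of 16, adjusted p = 0.757) and the immediate-early and stress list (3 higher and 6 lower of 17, adjusted p = 0.723) did not pass. In them the de novo methyltransferase gene DNMT3B was 3.61-fold higher and the p53 target PMAIP1 higher by 2.81 on the log2 scale in p7. Adjusted over the list alone, the counts of 16 lists were the same as those given here. They were 4 higher and 17 lower for mesoderm, 3 and 12 for fibroblast and matrix, 2 and 18 for WNT, 1 and 16 for BMP, 1 and 5 for glycolysis, 3 and 7 for imprinted genes and 3 and 2 for p53 targets.

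**Figure D3:**
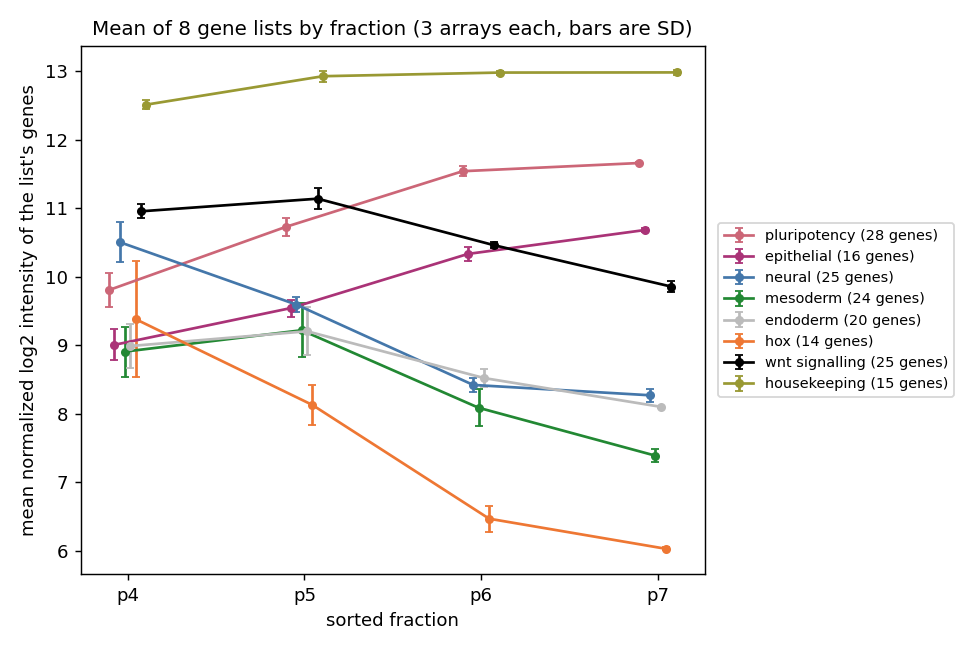
Mean normalized log2 intensity of the tested genes of 8 lists (y axis) in the 4 fractions (x axis), with bars for the SD over 3 arrays. The pluripotency list climbs from 9.81 in p4 to 11.66 in p7 and the HOX list falls from 9.38 to 6.03, while the mesoderm list stands at 8.91 in p4, 9.22 in p5 and 7.39 in p7.

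Fraction p6 was set against p4 as the first of the intermediate fractions. Among the named increases, GDF3 was 17.7-fold, CHST4 13.2-fold and EPCAM 12.7-fold higher in p6. MIXL1 and MGAT4C, detected on no p4 array, were at least 13.2-fold and 7.69-fold higher. NR2F1 fell by 6.08 on the log2 scale (SE 0.417), WNT1 was at least 28.6-fold lower, HOXC6 at least 21.2-fold, ZIC4 at least 24.3-fold and the melanin-synthesis gene TYRP1 at least 17.8-fold lower. CD9 was 6.44-fold, POU5F1 6.89-fold and PODXL 2.37-fold higher in p6 than p4 (adjusted p = 9.09e-07, 4.74e-06 and 0.00298), and SOX2 gave a log2 difference of -0.35 (adjusted p = 0.271). The other POU5F1 probe, not near the ceiling, gave a log2 difference of 4.50 against 2.78. Within slide 1 PODXL had a log2 difference of 1.22, against 1.24, and was not past the threshold (adjusted p = 0.199). Of the listed genes, 23 of 28 pluripotency genes were higher and none lower, 19 of 25 neural genes were lower and 1 higher, and 12 of 14 HOX genes were lower and none higher, with the same counts adjusted over the list alone. With them moved 12 lower and 3 higher of 23 fibroblast and matrix genes, 6 lower of 8 endothelial and blood genes (7 adjusted over the list alone), and 8 higher and 1 lower of 15 housekeeping genes. In total, 3031 genes were higher and 3164 lower in p6 (limma, adjusted p under 0.05). The counts were 3128 and 3283 with the slide as a block, 1088 and 1197 within slide 1, and 2304 and 2061 within slide 2.

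The step from p4 to p5 was the first between neighbouring fractions. DKK4, a secreted WNT antagonist, was 11.5-fold higher in p5 (log2 difference 3.52, SE 0.449), and MIXL1, detected on no p4 array, was at least 8.50-fold higher. The cytoplasmic actin gene ACTG1 was 6.89-fold, the beta-catenin gene CTNNB1 6.46-fold and CER1, a NODAL antagonist, 6.07-fold higher. IGF2 was 6.34-fold lower in p5, the retinal homeobox gene RAX 6.30-fold, the minor spliceosomal RNA RNU6ATAC 6.03-fold, the somatostatin gene SST 6.03-fold and COL6A3 5.98-fold lower. CD9 rose 3.35-fold (adjusted p = 9.93e-05), POU5F1 3.35-fold (adjusted p = 0.000469) and PODXL 2.09-fold (adjusted p = 0.0142), and SOX2 gave a log2 difference of -0.34 (adjusted p = 0.334). The other POU5F1 probe gave a log2 difference of 2.97 against 1.74. Within slide 1 POU5F1 and PODXL had log2 differences of 1.93 and 0.93, against 1.74 and 1.06, and neither was past the threshold (adjusted p = 0.0568 and 0.284). Nor were ACTG1 (2.84), CER1 (2.75), RAX (-2.58) and RNU6ATAC (-2.29) there, with adjusted p from 0.0556 to 0.0575. Without p5 replicate 2 PODXL had 0.98 (adjusted p = 0.0513) and SOX2 passed, with a log2 difference of -0.67 (adjusted p = 0.0343). Of 28 pluripotency genes 19 were higher and none lower, and of 25 neural genes 15 were lower and 1 higher. Of 24 mesoderm genes 5 were higher and 1 lower. Adjusted over the list alone these counts were 20 and 0, 16 and 1, and 4 and 1. The housekeeping list had 6 of 15 genes higher and none lower, the same adjusted over the list alone. Of 23 fibroblast and matrix genes 5 were lower and 1 higher, and of 8 endothelial and blood genes 3 were lower and none higher. Those counts were also the same over the list alone.

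Between p4 and p5, 1861 genes were higher and 1832 lower in p5 (limma, adjusted p under 0.05). With median scaling in place of quantile normalization the split was 1709 higher and 724 lower, so that 70.2% of calls were higher against 50.4%. The counts were 2021 and 2038 with the slide as a block, 113 and 31 within slide 1, and 840 and 591 within slide 2. Leaving out p5 replicate 2, p5 replicate 3 or p4 replicate 1 took the lower count to between 1167 and 1196.

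The step from p5 to p6 was the second between neighbouring fractions. NR2F1 fell by 4.61 on the log2 scale (SE 0.417), POU3F2 was at least 17.1-fold lower in p6, ZIC4 at least 8.46-fold, LIX1 at least 8.34-fold and LUM at least 7.30-fold lower. GDF3 rose 4.80-fold, the sulphotransferase gene CHST4 4.07-fold, the immune co-receptor ligand gene HHLA2 4.00-fold, the small GTPase gene RIT2 3.84-fold and GLB1L3 at least 2.67-fold. CD9 was 1.92-fold higher (adjusted p = 0.00425) and POU5F1 2.06-fold higher (adjusted p = 0.0120), while PODXL gave a log2 difference of 0.18 (adjusted p = 0.713) and SOX2 one of -0.01 (adjusted p = 0.990). Of 24 mesoderm genes 16 were lower and 1 higher, of 20 BMP genes 12 were lower and none higher, and of 28 pluripotency genes 18 were higher and none lower. Adjusted over the list alone the counts were 17 and 2, 12 and 0, and 20 and 0. Of 23 fibroblast and matrix genes 6 were lower and 1 higher (7 and 1 over the list alone). Of 8 endothelial and blood genes 1 was lower and none higher (2 lower over the list alone). None of 15 housekeeping genes was called. In total, 703 genes were higher and 937 lower in p6 than p5 (limma, adjusted p under 0.05), or 335 and 742 with median scaling, where 31.1% of calls were higher against 42.9%. The counts were 806 and 1048 with the slide as a block, 0 and 0 within slide 1, and 133 and 204 within slide 2. Slide 1 held 1 p6 array, and the log2 differences of CD9 and POU5F1 there were 0.99 and 0.98, against 0.94 and 1.04. The other POU5F1 probe gave 1.53 over all arrays. Without p6 replicate 1 the counts were 335 and 570, and without p5 replicate 1, p5 replicate 2 or p6 replicate 2 the higher count was 454, 407 or 421.

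Fractions p6 and p7 were the closest pair. FLRT3, a fibronectin leucine-rich transmembrane protein gene, was the gene called, 2.82-fold lower in p7 (10.06 ± 0.16 against 8.56 ± 0.10, SD, n = 3 each, limma adjusted p = 0.00266). No gene was called higher. At an unadjusted p under 0.05, 1589 genes passed, 736 higher and 853 lower, against a total of 568.6 expected by chance. CD9 gave a log2 difference of -0.04 (SE 0.169, adjusted p = 0.939), POU5F1 one of 0.21 (SE 0.228, adjusted p = 0.715), PODXL one of 0.00199 (SE 0.276, adjusted p = 0.999) and SOX2 one of -0.08 (adjusted p = 0.910). The brighter POU5F1 probe had a raw signal above 50000 on 2 p6 arrays and 3 p7 arrays, near the scanner's ceiling, which limits its difference. The other probe, whose highest raw signal was 20516.9, gave 0.13 (adjusted p = 0.901). None of the genes of any list passed over all genes tested. Adjusted over the list alone, 13 of 24 mesoderm genes and 12 of 25 WNT genes were lower in p7 with none higher, 7 of 20 endoderm genes were lower with none higher, and 4 of 16 epithelial genes were higher with none lower. The list means of mesoderm genes were 8.09 ± 0.27 in p6 and 7.39 ± 0.09 in p7 (SD, n = 3 each).

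The count of genes between p6 and p7 moved with the model. With the replicate number as a block, so that p6 and p7 of the same number were compared with each other, 24 genes were higher and 82 lower in p7. With the slide as a block the counts were 3 and 20, and within slide 1 and within slide 2 no gene was called. FLRT3 had log2 differences of -1.77 and -1.36 there, against -1.50. Leaving out p4 replicate 2, an array of neither fraction, gave 2 and 23. That removal also reran the normalization, the detection filter and the choice of probes. The shared spread alone therefore need not explain the change.

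The last comparison asked whether the first step of the series, p4 to p5, differed from the last, p6 to p7. DKK4 had a difference between the steps of 5.88 on the log2 scale (SE 0.635, limma adjusted p = 0.000571), with intensities of 6.81 ± 0.98, 10.33 ± 0.68, 10.24 ± 0.17 and 7.87 ± 0.43 from p4 to p7 (SD, n = 3 each). CER1 had a difference of 3.85. On the other side stood ANXA1 with -3.63, COL6A3 with -3.00 and CREB5 with -2.88. MIXL1, CUZD1 and LOX were also called with a positive difference, and HSD17B2 and RAX with a negative one. MIXL1 and CUZD1 were detected on no p4 array, LOX on no p7 array, and HSD17B2 and RAX on no p6 or p7 array, so the sizes of their differences are not resolved. The calls of ANXA1 and RAX (adjusted p = 0.0467 and 0.0388) were close to the threshold. ANXA1 was not past it in 9 of 12 removals of a single array (adjusted p up to 0.101) and RAX in 10 of 12 (adjusted p up to 0.0847), nor was either with the authors' values (adjusted p = 0.0572 and 0.0532). CREB5 was not past it without p5 replicate 2 or without p6 replicate 2 (adjusted p = 0.0535 and 0.0530). The difference was positive for 12 of 28 pluripotency genes and negative for none, and positive for 10 of 24 mesoderm genes and negative for none. A positive value can come from a rise in the first step or a fall in the last: the mesoderm list mean changed by 0.31 from p4 to p5 and by -0.70 from p6 to p7. Adjusted over the list alone these counts were 15 and 1, and 11 and 1. In total the steps differed for 2489 genes, 1380 with a positive and 1109 with a negative difference. The total was 2853 with the slide as a block, 0 within slide 1 and 902 within slide 2, and it was 1588 without p5 replicate 3 and 1594 without p7 replicate 3.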

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

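The 2 tests of fibroblasts or feeder cells in p4, the test of RNA quality and the test of slides for genes highest in p5 were chosen only after the results were seen, as were the counts of genes highest or lowest in p5.

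Detected probes without a single gene symbol entered no main comparison, only the alternative that tested every probe on its own. Among them, 1566 of 3126 differed between p7 and p4 (limma, adjusted p under 0.05), 775 higher and 791 lower. This is a signal in data outside the main measurement. The share, 50.1%, lay below the 56.8% of the 12615 detected probes with 1 symbol. Their log2 differences reached 5.02 and -5.86. What these probes measure was not worked out, and no biological explanation was tested.

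Genes that were highest in p5 were looked at because p5 lay between p4 and p6 on the axis over all genes: 42 genes were higher in p5 than in both p4 and p6, and 14 were lower than in both. Among the 42, chosen after their values were seen, were LOX (7.30, 9.29, 6.90 and 5.23 from p4 to p7, not detected in p7) and SOX17 (10.64 in p5 and 6.98 in p7). Uneven placing of p5 and p6 over the 2 slides is argued against, since 36 of the 42 genes were called with the slide as a block, although within slide 1 there were 0 and within slide 2 there were 8. A mixture of p4 and p6 cells in p5 could not exceed both, but 0 genes passed when the larger of the 2 one-sided p was adjusted over all genes, and 1, SNAI2 (adjusted p = 0.0331), with the replicate block, a test chosen after the result was seen. With both blocks 0 passed, so such a mixture stays open. A p5 state of its own is the biological alternative and stays open too: 0 of the 23 lists passed Fisher's exact test among the 42 genes (mesoderm 2 of 24, adjusted p = 0.0803).

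Neural, mesoderm, HOX and matrix genes were higher in p4 than p7, and fibroblasts or feeder cells among the p4 cells were weighed against differentiated progeny of the line itself. Fibroblasts are not known to carry neural transcripts such as PAX6 and POU3F2, which argues against them as the whole source of the neural part. That count is also part of the pattern, so it says nothing about any other source. For the matrix part 12 of 23 fibroblast and matrix genes were lower in p7, and fibroblasts and matrix-forming progeny cannot be told apart there. Some fibroblast transcripts were chosen after their values were seen. VIM gave a log2 difference of -0.28 and SPARC one of -0.75, neither past the threshold. THY1 and COL6A2 were higher in p7, by 1.22 and 1.36. Among the 12 lower genes were COL1A1, COL5A1 and ACTA2, with log2 differences of -1.64, -1.84 and -2.09. The COL1A2 probe was detected on 0 arrays, so COL1A2 was not tested. A sort on GCTM-2 and CD9 may keep feeder cells out of fractions gated on those antigens, but the gate of p4 is not given, and differentiated progeny remains an untested explanation.

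ACTB and ACTG1 were higher in p7 than p4, by 2.52 and 3.45 on the log2 scale, while GAPDH (-0.14) and TBP (0.01) were not past the threshold. ACTG1 in this comparison, GAPDH and TBP were chosen after their values were seen, and GAPDH changed sign with median scaling (0.00354). The scaling between arrays is argued against, since ACTB, the smaller of the pair, was at 2.66 with median scaling, the alternative that replaces quantile normalization, and at 2.47 or more over 4 alternatives to the processing. Lower RNA quality in p4 cannot be told apart from a change in the cells: the median of the 14 other housekeeping genes was 0.26, but actin probes may respond to RNA quality more than others. A difference in actin expression between the fractions is the biological alternative and was not tested further.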

How the results depend on the processing

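The alternatives were planned before the data were examined, except those for genes highest or lowest in p5, chosen after that result was seen. Named genes kept direction and side of the threshold in 4546 comparisons with an alternative, lost the call in 147, gained it in 1 and changed sign in 18, and lists did so in 688, 31, 12 and 3. With the replicate block no named gene or list changed its side of the threshold, and only the counts between p6 and p7 and those of genes highest or lowest in p5 moved by over 1.5 times. A stricter threshold or a 2-fold limit gives fewer calls by construction, and for the other changes the cause was not tested. With probes detected on all 12 arrays the housekeeping list lost its call at an unchanged mean of 0.47 (camera adjusted p = 0.0595). The imprinted list gained a call there (camera adjusted p = 0.0480). For p7 against p6 (higher and lower, 0 and 1), the counts were 2 and 10 with normexp at an offset of 50, 3 and 10 without background correction, 0 and 37 with median scaling, 1 and 19 with the authors' values, 2 and 17 for probes detected on all 12 arrays, 3 and 20 with the slide block, 24 and 82 with the replicate block, 28 and 68 with both blocks, 3 and 32 with only the groups compared, 56 and 140 with array weights, and 22 lower with trended and robust variances. Median scaling gave 724 lower in p5 than p4, 335 higher in p6 than p5 and 1454 for the difference of steps. With only the groups compared 1168 genes were lower in p5 than p4, and with array weights 1189 were higher in p6 than p5. Within slide 1 (6 arrays) the F-test called 1603 genes, p7 against p4 1221 and 1462, p6 against p4 1088 and 1197, p5 against p4 113 and 31, and p6 against p5, p7 against p6 and the difference of steps 0 each. Within slide 2 these were 3585 for the F-test, 2061 lower in p6 than p4, 840 and 591 for p5 against p4, 133 and 204 for p6 against p5, 0 for p7 against p6 and 902 for the steps. An adjusted p under 0.01 left 1063 and 782 for p5 against p4, 244 and 455 for p6 against p5 and 773 for the steps. A 2-fold difference left 2543 for the F-test, 1043 and 1239 for p7 against p4, 976 and 1071 for p6 against p4, 456 and 280 for p5 against p4, 138 and 385 for p6 against p5 and 883 for the steps. Of the lists, 6 shifted for probes detected on all 12 arrays, 0 with an estimated correlation and 18 with fry. Testing every probe put p5 at 0.471.

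Leaving out each array or replicate number in turn gave 4241 to 6529 genes for the F-test, 2458 to 3246 higher and 2533 to 3267 lower for p7 against p4, 2225 to 3046 and 2344 to 3162 for p6 against p4, 883 to 1938 and 590 to 1847 for p5 against p4, 152 to 783 and 350 to 983 for p6 against p5, 0 to 3 and 0 to 23 for p7 against p6, 188 to 2770 for the steps, 10 to 11 lists, and positions of 0.414 to 0.444 for p5 and 0.877 to 0.912 for p6. Single arrays moved counts by over 1.5 times. Lower in p5 than p4 were 1173 without p4 replicate 1, 1167 without p5 replicate 2 and 1196 without p5 replicate 3. Higher in p6 than p5 were 454 without p5 replicate 1, 335 (570 lower) without p6 replicate 1, 407 without p5 replicate 2 and 421 without p6 replicate 2. For p7 against p6 the counts were 3 and 21 without p4 replicate 1, 1 and 16 without p5 replicate 1, 0 and 3 without p6 replicate 1, 2 and 23 without p4 replicate 2, 0 and 2 without p7 replicate 2, 2 and 12 without p4 replicate 3, and 1 and 8 without p5 replicate 3. The steps differed for 1588 genes without p5 replicate 3 and 1594 without p7 replicate 3. FLRT3 lost its call without replicate 1, 2 or 3 in all fractions (adjusted p = 0.0932, 0.183 and 0.166) with log2 differences of -1.36, -1.52 and -1.61, against -1.50. Genes highest in p5 ranged from 5 to 44, with 20 without p5 replicate 1, 24 without p5 replicate 2, 27 without p6 replicate 1, 25 without p6 replicate 2 and 26 without p6 replicate 3, and numbered 75 with the replicate block. These signs changed for values not past the threshold. CD9 between p6 and p7 was 0.00999 with median scaling, 0.0776 within slide 2, and -0.147 to 0.0786 over the removals. PODXL between p6 and p7 was -0.0447 within slide 2 and -0.0682 to 0.0792 over the removals. SOX2 between p5 and p6 was 0.16 with both blocks and -0.29 to 0.43 over the removals, and between p6 and p7 -0.20 to 0.0689. The FGF list mean was -0.0994 for probes detected on all 12 arrays. Over the removals the p53 list mean was -0.0346 to 0.25 and the immediate-early list mean -0.12 to 0.00205. Another probe changed the sign of 2 called genes between p4 and p7: PRDM1 from -1.31 to 0.10 (adjusted p = 0.00889 and 0.800) and PKM from -0.73 to 0.98 (adjusted p = 0.0278 and 0.00873). Signal over background limits dim genes, and SOX2 was at most partly detected outside p4.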

Other observations

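The splits of the samples were planned before the data were examined, except for those of the genes highest in p5, which were chosen only after that result was seen. For each pair of fractions the 6 arrays make 10 splits of 3 against 3, too few for a share under 0.05, and the real split was the 1 with the highest count each time. For p7 against p4 it gave 6463 genes, for p6 against p4 6195, for p5 against p4 3693, for p6 against p5 1640 and for p7 against p6 1, and the highest other split gave 0 in each case. For the lists between p7 and p4 the real split gave 11 and the highest other 10, or 7 among the 4 of 10 splits that part all replicate pairs.

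For the 12 arrays, 100 splits into 4 groups were drawn, the real one included. Because the numbers pair the samples, 100 splits with each replicate number once in each group were drawn as well, a choice made after the first were seen. For genes differing among the fractions, 1 of 100 gave as many as the real 6644, a share under 0.05. The highest other split gave 4089, or 5823 among the paired splits. Splits that mix the fractions add the differences between fractions to the spread, and most called few or no genes. The share thus reflects the structure of the samples and does not by itself exclude chance. For genes whose first and last steps differ, 2 of 100 gave as many as the real 2489 (highest other 4319), and 3 of 100 paired splits did (highest other 6170). For genes higher in p5 than in p4 and p6, 3 of 100 gave as many as the real 42 (highest other 1677), and 3 of 100 paired splits did (highest other 1405). These shares are under 0.05, but the p5 count was chosen after it was seen, and 0 of its genes passed the joint test, or 1 with the replicate block. The unpaired splits with more genes than the real one in the step or p5 counts kept the 3 p4 arrays in 1 group and mixed the other fractions. So did the paired ones, except that 1 of them kept p5 whole as well and another, with 4817 step genes, mixed p4 only with p5 and p6 only with p7. Such splits point to the structure of the samples.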
